A study of Mus musculus with 22 samples.

How the data were processed

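RNA was measured in male mouse embryonic stem cells (ESCs) derived from the inner cell mass and kept without feeder cells in medium with serum and LIF, per the labels' protocols. Libraries were made from total RNA after removal of ribosomal RNA by RNase H and sequenced as paired-end reads on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name bcl2fastq, STAR 2.7, Bowtie2, RSEM and the build mm10. Their order, the counting tool, the annotation, the use of strand and the handling of reads that map to several places are not given in the sources used here. The authors deposited 1 table of whole-number counts per gene or repeat family, unscaled, for 22 libraries and 44749 entries, of which 43672 match GENCODE vM21 symbols and 1077 are repeat families. The authors also deposited a table of normalized signal, in which each count is divided by 1 factor per library: over the 34971 complete lines the largest relative deviation from such a factor was 5.44e-15. How those factors were made is not given in the sources used here. The normalized table as held ends in the middle of a line and served only as an alternative scaling.

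The titles give 12 groups. 8 libraries come from Ythdc1 conditional knockout (cKO) cells of 2 ESC lines, treated with 4OHT or DMSO. The columns of the count table number these libraries 1 to 4 per treatment and carry no ESC line, so the libraries were compared as 4 against 4. In log2 CPM of 10628 well expressed entries, libraries of the same column number deviated together from their group means (correlation 0.33, 0.115, 0.34 and 0.385 for numbers 1 to 4), so by the data these numbers pair the libraries. What a number marks is not given in the sources used here, and the fit with it as a replicate block was an alternative. The comparisons within each line, the difference between lines and the additive line model, which had been laid out before the data were examined, were therefore not run. 4 libraries are Mettl3 knockout (KO) or wild type (WT), 2 of each. 10 libraries combine Ythdc1 cKO with Dux-Het, Dux-KO or no Dux label. For these 10 the genotype and treatment fields in the labels are shifted by 1 sample against the titles. The titles were used, and they match the column names. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples.

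Total counts per library ran from 24.96 to 54.14 M. 3 counts over a group set the floor for a gene at 0 in every library of that group, and the fold is then given as at least the ratio to that floor. No fold is given where both groups hold 3 counts or fewer. Between 2 libraries of 1 group the chi-square per degree of freedom, over entries with at least 20 counts, ran from 3.741 to 99.07 in 18 pairs, above counting error, so tests rest on the spread between libraries. Intervals and floors cover counting error only.

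Differences were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM scaling, glmQLFit and glmQLFTest), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. All adjusted p-values for genes come from this quasi-likelihood test. Standard errors of log2 fold changes are the absolute log2 fold change over the square root of the F statistic. The Ythdc1 set (8 libraries), the Mettl3 set (4) and the Dux set (10, as 6 group means that share 1 estimate of the spread) were fitted apart, and 1 further fit of 12 libraries tested the Ythdc1 effect minus the Mettl3 effect. Levels are depth-scaled CPM with 1 TMM scaling over all 22 libraries, given as mean ± SD. Gene positions are from GENCODE vM21 on GRCm38 (mm10). The pair of libraries with no Dux label has 1 library per treatment and no test. It is described by log2 ratios with a pseudocount of 0.5 CPM, by 95% exact Poisson intervals, and by the percentile of each list's median among 10000 random lists matched on expression.

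17 gene lists were fixed before the data were examined: two-cell-like genes, pluripotency genes, formative and primed epiblast genes, primitive endoderm genes, trophectoderm genes, mesoderm genes, neural genes, fibroblast and feeder genes, m6A writer, reader and eraser genes, heterochromatin and retroelement silencing genes, p53 target genes, integrated stress response genes, interferon-stimulated genes, ribosome biogenesis genes, germline genes, mitochondrially encoded genes and retroelement families. Dux is present as Duxf3. Cml2, Tcstv2, Afp, Prl3d1, 1110037F02Rik and IAPEY-int were not found in the table. Lists with at least 4 tested members were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and adjustment over the lists of a comparison. An estimated correlation and fry were the alternatives. Of these 17 lists none kept its camera call with an estimated correlation except two-cell-like genes in Dux-KO against Dux-Het under 4OHT. A count "adjusted over the list alone" repeats the adjustment among the list's members. Lists for sterol synthesis and glycolysis were chosen after the data were seen and adjusted over these lists alone.

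Genes were named by a rule fixed before the data were examined: the targeted genes, in each main comparison the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold, with an average log2 CPM of at least 1 and no overlap between the compared libraries, up to 4 members per list with the smallest adjusted p, members with a defining role (Pou5f1, Nanog, Sox2, Zscan4c, Zscan4d, Cdkn1a, Gata6, Cdx2), and MERVL-int, MT2_Mm, IAPEz-int, L1Md_T and L1Md_A. Symbols made of Gm and digits, ending in Rik or -ps, or naming clones were left out of the largest changes. A gene named beyond the rule is marked as chosen after its values were seen. Some genes that the rule takes are not reported here.

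The fits were tested on a single set of simulated counts per comparison, at the real means and depths. In each, 66 or 67 well expressed genes per fold were changed. These are far fewer genes than passed in the real Ythdc1, Mettl3, Dux-Het and Dux-KO comparisons, so the shares below need not hold there. In the Ythdc1 set (24385 genes) 53.7% of 1.5-fold, 86.6% of 2-fold and 100% of 4-fold changes were recovered. In the Mettl3 set (23977 genes) these were 29.9%, 73.1% and 97%. In the Dux set (29322 genes) they were 5.97%, 29.9% and 89.4% in Dux-Het, 2.99%, 40.3% and 90.9% in Dux-KO, and 0%, 11.9% and 63.6% for the difference between genotypes. Of the simulated calls 4.76% were false in the Ythdc1 set and 3.62% in the Mettl3 set. In the Dux set 12 of 95 calls (12.6%, Dux-Het), 8 of 97 (8.25%, Dux-KO) and 9 of 59 (15.3%, difference between genotypes) were false. These shares lay above the nominal 5%, so counts there may be less exact, but they rest on few calls.

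Alternatives laid out before the data were examined were DESeq2 1.42.0, RLE size factors, no filter, a mean of at least 5 CPM, a test against a 1.5-fold change, the replicate number as a block, fits of 1 genotype alone or of all samples, and leaving out each library. Chosen after seeing the data were the authors' factors, gene entries without repeats, and the table without 5 entries that resemble ribosomal or 7SL RNA. So were the Dux set without 2 DMSO libraries (Dux-Het replicate 2 and Dux-KO replicate 1) and the column number as a block in the Ythdc1 set. Pseudocounts of 0.1 and 1 CPM for the pair with no Dux label were chosen then as well. The spread within a group of 2 libraries does not show which of them stands apart. The targeted genes are a weak check of the labels: counts per gene include exons outside a deletion, and the position of each deletion is not given in the sources used here. Counts of near-identical copies (Zscan4, Usp17l, Duxf3 and the repeat families) are uncertain, since the assignment of shared reads is unknown. Mir5114 lies inside Scd2, and no count here separates it from its host. Sites of m6A, splicing and single repeat copies were not analysed here.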

Results

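RNA-seq counts were compared in mouse ESCs labelled as conditional knockouts of Ythdc1, a nuclear reader of the RNA modification m6A, and in ESCs labelled as knockouts of Mettl3, the catalytic subunit of the m6A writer. Further libraries came from Ythdc1 cKO cells with 1 (Dux-Het) or no (Dux-KO) working allele of Dux, the transcription factor that turns on genes of the two-cell embryo. The Dux gene stands in the table as Duxf3. Ythdc1 cKO cells were treated with 4OHT, a ligand used to activate inducible Cre recombinases, or with DMSO as the control. Total counts were 37.77 to 51.43 M in 4 Ythdc1 cKO libraries under DMSO and 32.23 to 48.85 M in 4 under 4OHT, 24.96 to 28.66 M in 2 Mettl3 WT and 26.2 to 26.38 M in 2 Mettl3 KO libraries. They were 43.44 to 44.77 and 43.02 to 52.21 M in the Dux-Het libraries under DMSO and 4OHT (2 each). Totals were 31.64 to 47.36 and 49.51 to 54.14 M in the Dux-KO libraries (2 each), and 38.18 and 43.43 M in a pair with no Dux label (1 each). The labels' fields for the Dux libraries are shifted by 1 sample against their titles, and the titles were used. Values are mean CPM ± SD of the deposited counts, and adjusted p-values are from edgeR's quasi-likelihood test over all genes tested.

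To ask what loss of Ythdc1 changes in ESCs, 4OHT was compared with DMSO (n = 4 each). Genes of the two-cell embryo rose: Zscan4c, a telomere-regulating gene of that stage (chromosome 7, 11005745 to 11010547 on mm10), went from 6.37 ± 3.96 to 45.6 ± 14.6 CPM (7.38-fold, log2 fold change 2.88, SE 0.294, adjusted p = 8.64e-07 by edgeR's quasi-likelihood test). Zscan4d rose 10.5-fold from 2.65 ± 2.11 CPM. Duxf3 itself (chromosome 10, 58229979 to 58232675) rose from 0.234 ± 0.0718 to 1.13 ± 0.404 CPM (4.95-fold, adjusted p = 0.000193). Of 37 two-cell-like genes 35 rose, Eif4e3 fell and Ubtfl1 did not pass, with a median log2 fold change of 3.02. The list passed as a whole (camera adjusted p = 2.8e-14, adjusted p = 0.372 with an estimated correlation). MERVL-int, the internal part of the endogenous retrovirus active at the two-cell stage, went from 628 ± 82.3 to 1917 ± 503 CPM (3.14-fold, SE of the log2 fold change 0.133), and its promoter MT2_Mm rose 2.74-fold. Of 22 retroelement families 21 rose and MMVL30-int did not pass (median 0.50, camera adjusted p = 7.29e-13, adjusted p = 0.186 with an estimated correlation). Among them were MMERVK10C-int (log2 fold change 1.18), L1Md_T (0.58), L1Md_A (0.45) and IAPEz-int (0.36). In all, 637 of 1032 repeat families rose and 8 fell. GSAT_MM, the major satellite of pericentric heterochromatin, rose 11.1-fold in this set (named after its values were seen). It also rose in the Mettl3 set (log2 fold change 1.19, adjusted p = 0.00637 by edgeR) and did not pass in Dux-Het (0.95, adjusted p = 0.401) or Dux-KO (1.17, adjusted p = 0.287). Replicate 1 of the DMSO group stood apart from the other 3 (chi-square per degree of freedom 30.97 to 37.05, against 8.441 to 10.82 among them) and held the most Zscan4 counts of the group (61.71 CPM summed over 9 genes, others 12.22 to 27.05). Repeat families held 23 ± 1.18% of counts under DMSO and 27.94 ± 0.734% under 4OHT.

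Ythdc1 transcripts (chromosome 5, 86804221 to 86836659) fell by 0.41 in log2 (SE 0.0812, adjusted p = 0.00064 by edgeR), from 77.1 ± 4.56 to 56.6 ± 6.78 CPM. Mettl3 did not pass (35.9 and 38.7 CPM, adjusted p = 0.132). Targets of the tumor suppressor p53 rose: Mdm2, which degrades p53, went from 97.39 ± 15.9 to 342 ± 29.2 CPM (3.61-fold, SE of the log2 fold change 0.0921, adjusted p = 5.11e-10). Cdkn1a, which arrests the cell cycle, rose from 75.8 ± 3.78 to 157 ± 13.1 CPM (2.12-fold). Of 23 p53 target genes 20 rose, Sesn1 and Xpc fell and Rrm2b did not pass (median 0.91, camera adjusted p = 9.01e-13, adjusted p = 0.162 with an estimated correlation). Among the largest falls were Scd1, a desaturase that makes monounsaturated fatty acids (150.5 ± 31.7 to 6.96 ± 2.9 CPM, 20.9-fold lower, adjusted p = 5.62e-10), and its paralog Scd2 (642 ± 39.3 to 73.2 ± 16.2 CPM, 8.54-fold lower) with Mir5114 inside it (log2 fold change -2.78). Others were Slfn9 (-3.54), Ndufa4l2 (-2.97), Ndrg2 (-2.885) and Gbp7 (-2.88). The largest rises were in Nav3 (0.447 ± 0.209 to 12.1 ± 3.68 CPM, log2 fold change 4.78), Fbp2 (4.51), Adamts3 (4.32), Adcy10 (4.30), Ltb4r1 (4.26), Dok6 (4.145), Nfam1 (4.14) and Adcy4 (3.89). By edgeR 11008 of 24385 genes and repeat families passed, 5783 higher and 5225 lower. Of these 2225 and 944 changed at least 2-fold.

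Among pluripotency genes Nanog, a core factor of naive cells, fell from 280.5 ± 14.5 to 99.97 ± 17 CPM (2.73-fold lower, SE of the log2 fold change 0.0946, adjusted p = 7.76e-09 by edgeR). Pou5f1 (log2 fold change -0.17, adjusted p = 0.0936, or 0.00857 with the column number as a replicate block) and Sox2 (0.04, adjusted p = 0.679) did not pass. Of 26 pluripotency genes 6 rose and 11 fell (7 and 12 adjusted over the list alone), with Tcl1 (-1.48), Fgf4 (-1.07) and Dppa2 (0.97) among them. The list test gave no call (median -0.21, camera adjusted p = 0.0588), but did with the replicate block (camera adjusted p = 0.028, adjusted p = 0.702 with an estimated correlation). Formative and primed epiblast genes went both ways, 5 higher and 9 lower of 15 (camera adjusted p = 0.357). The Nodal inhibitors Lefty1 (-2.07) and Lefty2 (-2.57) fell and Nodal (0.83) rose. Of 18 primitive endoderm genes 12 rose and none fell (13 adjusted over the list alone). Among them were the basement membrane genes Col4a1 (1.14) and Sparc (0.87) and the lineage factor Gata6 (0.94, adjusted p = 0.0076). The list's median was 0.78 (camera adjusted p = 0.000195, adjusted p = 0.372 with an estimated correlation). Trophectoderm genes (3 rose and 4 fell of 18, median 0.04, mean -0.12, test lower, camera adjusted p = 0.737) included Tead4 (-1.27). Cdx2 did not pass (0.33, adjusted p = 0.372). Mesoderm genes (5 and 2 of 10, 5 and 3 adjusted over the list alone, camera adjusted p = 0.478) included Wnt3 (1.84), T (-1.45) and Fgf8 (-3.00). Neural genes (3 and 3 of 14, median 0.04, mean 0.08, test lower, camera adjusted p = 0.951) included Neurod1 (2.22) and Pax6 (-1.73). Fibroblast and feeder genes (4 and 2 of 12, 4 and 3 adjusted over the list alone, 5 and 4 with the replicate block, camera adjusted p = 0.735) included Acta2 (1.60) and Thy1 (-1.34).

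Of 21 m6A writer, reader and eraser genes 11 fell and none rose after 4OHT in the Ythdc1 set. Among them were Ythdc1 itself, the gene targeted in these cells, the m6A reader Igf2bp3 (-0.98) and the writer subunit Mettl14 (-0.40). The median was -0.16 (camera adjusted p = 0.00551, adjusted p = 0.326 with an estimated correlation). Of 27 heterochromatin and retroelement silencing genes 15 fell and 5 rose (16 and 5 adjusted over the list alone). Examples were the DNA methylation factor Uhrf1 (-0.75) and the chromatin assembly subunit Chaf1b (-0.89) down and Dnmt3l (1.39) up. The list test gave lower (median -0.22, camera adjusted p = 0.00903, adjusted p = 0.649 with an estimated correlation). Integrated stress response genes split, 9 up and 5 down of 19 (camera adjusted p = 0.48). The stress genes Chac1 (1.77) and Atf3 (1.48) rose while the serine synthesis genes Phgdh and Psat1 fell (-1.39 each). Interferon-stimulated genes (5 fell of 16, among them Oasl2, -1.61, camera adjusted p = 0.129) and ribosome biogenesis genes (10 fell and Nop58 rose of 25, camera adjusted p = 0.0509) passed no list test. With the replicate block both passed as lower (camera adjusted p = 0.047 and 0.0148, adjusted p = 0.27 and 0.727 with an estimated correlation). Germline genes (5 rose and 3 fell of 17, camera adjusted p = 0.737) and mitochondrially encoded genes (3 rose and 2 fell of 15, 4 and 7 with the replicate block, camera adjusted p = 0.688) did not pass either. Of 17 lists, 6 passed camera and 0 with an estimated correlation. The fry test, which compares a list with no other gene, called 10.

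To ask what loss of the m6A writer changes, libraries labelled Mettl3 KO were compared with WT (n = 2 each). Two-cell-like genes were among the largest rises: Zscan4d went from 0.275 ± 0.152 to 33.1 ± 1.24 CPM (log2 fold change 6.93, SE 0.243, adjusted p = 1.3e-06 by edgeR's quasi-likelihood test). Zscan4c rose from 0.33 ± 0.183 to 33.9 ± 2.71 CPM (6.70, SE 0.248), and Zscan4e, Zscan4f, Zscan4b and Zscan4a rose by 6.70, 6.61, 6.03 and 5.96. Duxf3 rose as well (2.63, SE 0.719, adjusted p = 0.021). Of 34 two-cell-like genes 31 rose, Eif4e3 fell, and Obox6 and Zfp750 did not pass. The median was 5.36, or 5.18 with 4 genes that had 0 WT counts taken at their lower bound (camera adjusted p = 2.08e-14, adjusted p = 0.379 with an estimated correlation). MERVL-int rose from 307 ± 8.93 to 622.5 ± 27.3 CPM (log2 fold change 1.03, SE 0.0711). Of 22 retroelement families 15 rose and 2, MMETn-int (-0.75) and ETnERV-int (-0.74), fell (16 and 2 adjusted over the list alone, median 0.58, camera adjusted p = 4.1e-05, adjusted p = 0.56 with an estimated correlation). L1Md_T (0.64), L1Md_A (0.63) and IAPEz-int (0.54) were among those that rose. In all, 110 of 1028 repeat families rose and 21 fell. The vomeronasal receptor gene Vmn1r46, with 0 counts in WT, rose at least 171-fold to 9.16 ± 2.5 CPM. The largest falls were in Halr1 (-4.69), Pla2g1b (-4.52), Fam19a4 (-4.12), Cubn (-4.04), Hydin (-3.98), Snap25 (-3.63), Ndufa4l2 (-3.615) and Plvap (-3.44).

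Mettl3 transcripts (chromosome 14, 52294841 to 52305128) did not pass: 29.3 ± 0.872 CPM in WT against 14.55 and 28.51 in the libraries labelled Mettl3 KO (log2 fold change -0.44, adjusted p = 0.207 by edgeR). Counts per gene include exons outside a deletion. KO and WT also differed in Kdm5d, a gene of the Y chromosome (log2 fold change 4.88, SE 0.222, adjusted p = 3.75e-06), with smaller values for the Y-linked genes Ddx3y (0.73), Eif2s3y (-0.34) and Uty (-0.22, adjusted p = 0.213; these 4 were named after their values were seen). Ythdc1 rose from 82.2 ± 1.94 to 145 ± 13.2 CPM (0.82, SE 0.0915, adjusted p = 0.000236), along with the cytoplasmic reader Ythdf2 (1.245) and the writer subunit Wtap (1.02). Of 21 m6A writer, reader and eraser genes 9 rose and 2 fell (10 and 6 adjusted over the list alone, camera adjusted p = 0.13). Nanog rose by 0.45 (SE 0.0829, adjusted p = 0.00321) and Klf2 by 1.17, and Tdgf1 fell by 1.62. Pou5f1 (0.12, adjusted p = 0.308) and Sox2 (-0.21, adjusted p = 0.224) did not pass. Of 26 pluripotency genes 10 rose and 9 fell (10 and 10 adjusted over the list alone, median -0.15, mean 0.00495, test lower, camera adjusted p = 0.82). Of 12 neural genes 4 fell and none rose, among them Pax6 (-2.575) and Elavl3 (-2.19). The median was -0.40 (camera adjusted p = 0.0175, adjusted p = 0.56 with an estimated correlation). Of 25 ribosome biogenesis genes 12 fell and 3 rose, with Npm1 at -0.60 and Bop1 at -0.80. The list passed (camera adjusted p = 0.000969, adjusted p = 0.56 with an estimated correlation). Of 23 p53 target genes 6 rose and 3 fell, with Mdm2 at 0.55 and Cdkn1a not past the threshold (0.30, adjusted p = 0.113). The median was 0.03 (camera adjusted p = 0.797).

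Other lists of the Mettl3 set did not pass camera. Formative and primed epiblast genes (3 rose and 5 fell of 15, camera adjusted p = 0.526) included Lef1 (-1.42). Primitive endoderm genes (6 and 1 of 16, 7 and 1 adjusted over the list alone, camera adjusted p = 0.117) included Col4a1 (1.10), and trophectoderm genes (3 and 2 of 17, camera adjusted p = 0.526) Hand1 (2.09) and Krt19 (-2.36). Mesoderm genes (3 and 2 of 10, 4 and 2 adjusted over the list alone, camera adjusted p = 0.526) included T (-2.47) and Snai1 (2.16). Gata6 (-0.62, adjusted p = 0.339 by edgeR) and Cdx2 (-0.28, adjusted p = 0.81) did not pass. Fibroblast and feeder genes (1 rose and 5 fell of 12, 2 and 5 adjusted over the list alone, camera adjusted p = 0.122) included Col1a2 (-2.04). Heterochromatin and retroelement silencing genes (5 and 11 of 27, 8 and 12 adjusted over the list alone, camera adjusted p = 0.321) included Cbx3 (-0.91) and Setdb1 (0.66). Integrated stress response genes (2 and 5 of 19, 4 and 6 adjusted over the list alone, median -0.13, mean 0.09, test lower, camera adjusted p = 0.321) included Shmt2 (-1.36) and Cebpb (2.30). Interferon-stimulated genes (2 and 4 of 18, 2 and 5 adjusted over the list alone, camera adjusted p = 0.333), germline genes (3 and 1 of 18, camera adjusted p = 0.526) and mitochondrially encoded genes (3 and 1 of 14, 4 and 1 adjusted over the list alone, camera adjusted p = 0.424) completed the 17. By edgeR 7492 of 23977 genes and repeat families passed in the Mettl3 set, 3928 higher and 3564 lower (4765 and 4951 without replicate 2 of KO). That count rests on each WT library: 351 passed without replicate 1 of WT and 1928 without replicate 2.

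The Ythdc1 and Mettl3 effects were compared directly. Across 22499 genes and repeat families the fold changes went together with r = 0.332 and rho = 0.207 (genes are not independent replicates). By edgeR 1350 were higher in both against 850 expected and 1599 were lower in both against 803 expected. Higher in the Ythdc1 set and lower in the Mettl3 set were 519 against 812 expected, and the other way 729 against 841 expected. The difference of the effects, tested in 12 libraries, passed for 7157 of 28260 by edgeR, 3874 higher and 3283 lower in the Ythdc1 effect than in the Mettl3 effect. That balance turned over with the authors' factors (3454 and 3592) and with gene entries alone (3376 and 3415). Zscan4c (-3.78, adjusted p = 7e-04 by edgeR) and Zscan4d (-3.50) rose less in the Ythdc1 set, from a higher control level. Of 40 two-cell-like genes 14 were lower and 2 higher in this difference (median -2.01, camera adjusted p = 0.133, or 0.011 with the replicate block, adjusted p = 0.716 with an estimated correlation). MERVL-int (0.67, adjusted p = 0.0244), MT2_Mm (0.86) and MMETn-int (1.33) rose more, as did 8 of 22 retroelement families in all (median 0.13, camera adjusted p = 0.0156, adjusted p = 0.803 with an estimated correlation). Of 23 p53 target genes 18 were higher and 1 lower (19 and 1 adjusted over the list alone), with Plk2 at 1.79, Ccng1 at 1.40 and Cdkn1a at 0.82. The list passed (median 0.82, camera adjusted p = 3.33e-11, adjusted p = 0.103 with an estimated correlation). Of 21 m6A genes 11 were lower and 1 higher, with Ythdf2 at -1.53 and Wtap at -0.88 (camera adjusted p = 8.76e-05, adjusted p = 0.11 with an estimated correlation). The targeted genes Ythdc1 and Mettl3 are members of that list. Nanog was lower (-1.86), and 5 of 14 neural genes were higher (6 adjusted over the list alone, camera adjusted p = 0.0273, adjusted p = 0.764 with an estimated correlation). The 2 effects were measured in different cells against different controls, and those differences are part of each value.

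**Figure D1:**
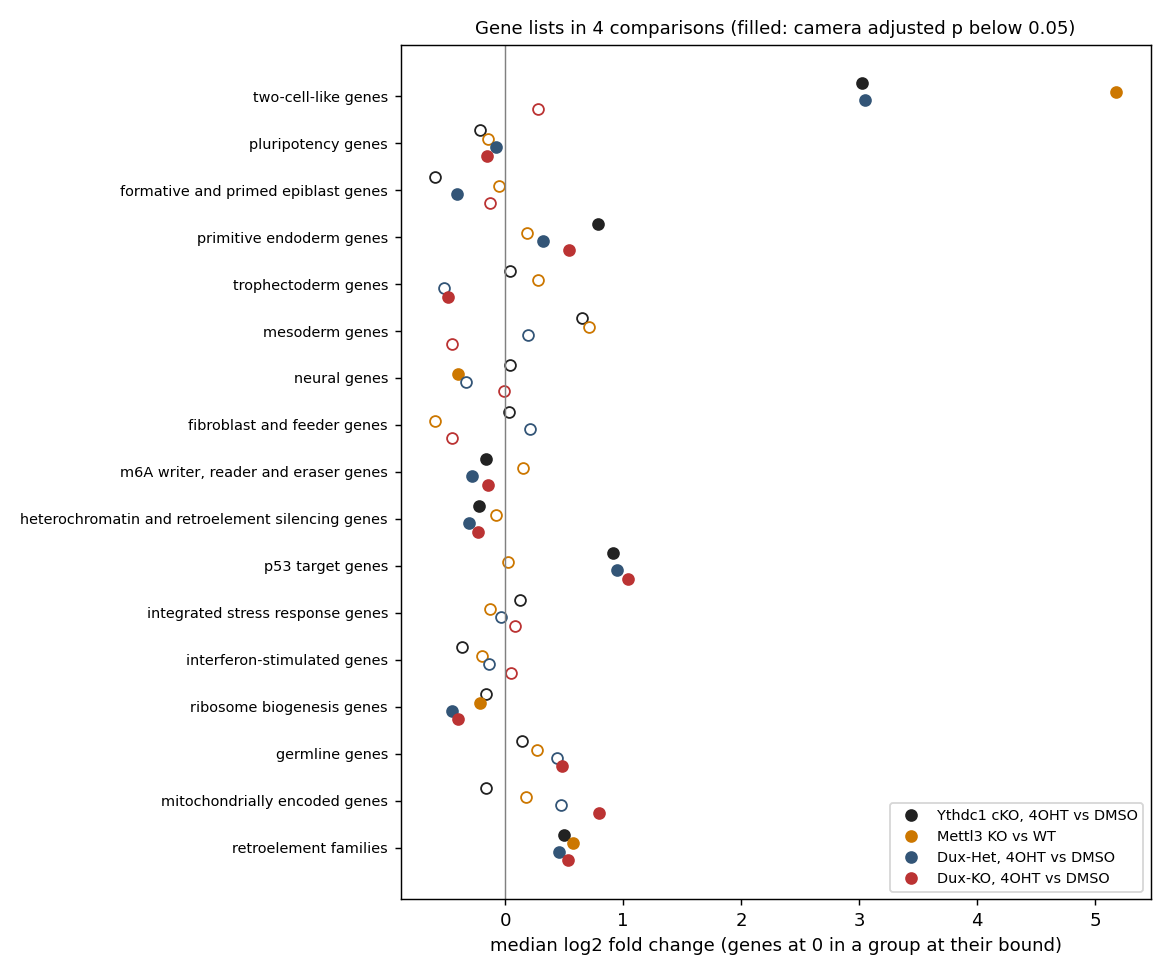
Median log2 fold change of 17 gene lists in 4 comparisons, with genes at 0 counts in a group taken at their bound; filled points have a camera adjusted p below 0.05. Two-cell-like genes had medians of 3.02 (Ythdc1), 5.18 (Mettl3), 3.05 (Dux-Het) and 0.28 (Dux-KO, over the 9 genes with more than 3 counts in a group).

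To ask whether these changes need Dux, 4OHT was compared with DMSO in Ythdc1 cKO cells that were Dux-Het (n = 2 each). Zscan4c rose from 2.37 ± 0.426 to 21 ± 0.837 CPM (log2 fold change 3.15, SE 0.244, adjusted p = 0.000195 by edgeR's quasi-likelihood test), and Zscan4d by 3.01. Duxf3 rose from 0.105 to 1.24 CPM (3.52, SE 0.637, adjusted p = 0.00713) and MERVL-int from 329 ± 24.1 to 959.9 ± 140 CPM (1.545, SE 0.161). Of 40 two-cell-like genes 30 rose and none fell (38 and 1 adjusted over the list alone). The median was 3.11, or 3.05 with 3 genes at their lower bound (camera adjusted p = 3.02e-27, adjusted p = 0.16 with an estimated correlation). Of 22 retroelement families 5 rose (9 adjusted over the list alone, median 0.46, camera adjusted p = 6.01e-07, adjusted p = 0.404 with an estimated correlation). Of 23 p53 target genes 17 rose (19 adjusted over the list alone), with Mdm2 at 2.36 and Perp at 2.50, and Cdkn1a rose from 35 ± 1.65 to 120 ± 5.95 CPM. The list passed (median 0.95, camera adjusted p = 5.55e-17, adjusted p = 0.111 with an estimated correlation). Scd2 fell 10.2-fold, from 436 ± 90.6 to 42.6 ± 1.63 CPM. Scd1 (-3.82), Ndufa4l2 (-3.32), Mir5114 (-3.21), Lipg (-3.19), Slfn9 (-3.10) and Dppa5b (-5.50) fell as well. Fosb (4.915), Anxa8 (4.69), Col20a1 (4.25), Nfam1 (4.23), Dnase1l3 (4.03), Muc15 (4.00), Adcy10 (3.89) and Tmem92 (3.73) rose most. Ythdc1 itself (72.1 ± 19.8 and 59.1 ± 9.28 CPM, adjusted p = 0.456) did not pass.

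Nanog fell by 0.65 in Dux-Het cells (SE 0.145, adjusted p = 0.0185 by edgeR). Of 26 pluripotency genes 6 fell and none rose (8 and 1 adjusted over the list alone, camera adjusted p = 0.0259, adjusted p = 0.322 with an estimated correlation). Formative and primed epiblast genes (1 rose and 2 fell of 15, 1 and 4 adjusted over the list alone) had a median of -0.41 (camera adjusted p = 0.028, adjusted p = 0.551 with an estimated correlation). Primitive endoderm genes (3 of 18 rose, Pdgfra at 1.33 and Gata6 at 1.41) had a median of 0.33 (camera adjusted p = 0.028, adjusted p = 0.518 with an estimated correlation). Of 27 silencing genes 7 fell and 1 rose (11 and 2 adjusted over the list alone), with the histone methyltransferase Ehmt2 at -1.18. The list passed (camera adjusted p = 0.000238, adjusted p = 0.18 with an estimated correlation). Of 25 ribosome biogenesis genes 7 fell (13 adjusted over the list alone), with Ncl at -0.72 (camera adjusted p = 7.62e-09, adjusted p = 0.188 with an estimated correlation). Of 21 m6A genes 2 fell, Igf2bp3 (-0.94) and Igf2bp2 (-1.01). That list passed as well (camera adjusted p = 0.00113, adjusted p = 0.316 with an estimated correlation). Lists of trophectoderm, mesoderm (median 0.19, mean -0.54, test lower), neural (median -0.33, mean 0.13, test lower) and fibroblast genes did not pass camera (adjusted p = 0.191, 0.706, 0.328 and 0.435). Nor did integrated stress response, interferon-stimulated, germline and mitochondrially encoded genes (adjusted p = 0.136, 0.37, 0.0884 and 0.188). Among these lists 1 trophectoderm gene fell, 1 mesoderm gene rose and 2 fell, 1 neural gene rose and 2 fell, 1 stress response gene rose and 6 fell, 1 interferon-stimulated gene fell and 2 germline genes rose. Adjusted over the list alone, 4, 4, 3, 6 and 0 of the trophectoderm, mesoderm, neural, stress response and interferon-stimulated genes fell and 1, 1, 1, 4 and 0 rose. For Ythdc1 4OHT vs DMSO in Dux-Het, 2738 of 29322 passed by edgeR, 1464 higher and 1274 lower (1618 and 1643 by DESeq2). The count was 1585 without its DMSO replicate 1, 1771 and 1254 without its 4OHT replicates 1 and 2, and 1519 and 1506 without Dux-KO 4OHT replicates 1 and 2, which share the estimate of the spread.

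The same treatment was compared in Ythdc1 cKO cells that were Dux-KO (n = 2 each). Zscan4c and Zscan4d had 0 counts in all 4 libraries, Duxf3 stood at 0.0746 and 0.055 CPM. Of 40 two-cell-like genes Zfp750 rose (1.91, SE 0.256, adjusted p = 0.0015 by edgeR's quasi-likelihood test). The other 39 did not pass, and 31 of the 40 held 3 counts or fewer in both groups. Over the 9 others the median was 0.28, and no test of the list is given. MERVL-int (262 ± 40.6 and 329 ± 3.54 CPM, log2 fold change 0.32, SE 0.157, adjusted p = 0.217) and MT2_Mm (0.26, adjusted p = 0.289) did not pass. ETnERV-int (1.25), MMERVK10C-int (0.92) and IAPEz-int (0.72) were among 8 of 22 retroelement families that rose (10 adjusted over the list alone, median 0.53, camera adjusted p = 3.51e-07, adjusted p = 0.466 with an estimated correlation). The DMSO replicates 1 and 2 stood far apart (chi-square per degree of freedom 99.07), with 16.39% and 20.78% of counts in repeat families. Under 4OHT these shares were 24% and 24.41%. Of 23 p53 target genes 19 rose and none fell (20 and 1 adjusted over the list alone). Mdm2 rose from 59.96 to 399.6 CPM (2.73, SE 0.184, adjusted p = 2.59e-05) and Cdkn1a from 36.5 ± 4.13 to 123 ± 4.92 CPM. The list passed (median 1.04, camera adjusted p = 3.83e-16, adjusted p = 0.109 with an estimated correlation). Scd2 fell from 476 ± 3.55 to 43.7 ± 0.824 CPM (-3.45, SE 0.171). With it fell Scd1 (-3.845), Ndufa4l2 (-3.56), Lipg (-3.43), Mir5114 (-3.295), T (-3.23), Slfn9 (-3.01) and Fat3 (-3.005). The largest rises were in Anxa8 (4.47), Col20a1 (4.26), Wnt8a (4.15), Cpz (4.005), Ltb4r2 (3.945), Nfam1 (3.90), Tbx4 (3.87) and Dnase1l3 (3.84). Ythdc1 (58.5 ± 14.4 and 55.3 ± 1.85 CPM, adjusted p = 0.843) did not pass.

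Nanog fell by 0.77 in Dux-KO cells (SE 0.145, adjusted p = 0.0094 by edgeR). Of 26 pluripotency genes 4 fell and 1 rose (10 and 2 adjusted over the list alone, camera adjusted p = 0.0138, adjusted p = 0.382 with an estimated correlation). Primitive endoderm genes (3 of 18 rose, 5 adjusted over the list alone, Hnf4a at 1.57) had a median of 0.54 (camera adjusted p = 0.0126, adjusted p = 0.509 with an estimated correlation). Trophectoderm genes (6 fell and 1 rose of 19, 7 and 2 adjusted over the list alone, Krt19 at -1.96) had a median of -0.49 (camera adjusted p = 0.0156, adjusted p = 0.509 with an estimated correlation). Silencing genes (5 fell and 1 rose of 27, 10 and 1 adjusted over the list alone, camera adjusted p = 0.00396, adjusted p = 0.304 with an estimated correlation) included Ehmt2 (-1.37). Ribosome biogenesis genes (3 of 25 fell, 11 adjusted over the list alone, camera adjusted p = 2.73e-05, adjusted p = 0.382 with an estimated correlation) included Nolc1 (-0.76). The m6A genes (2 of 21 fell, camera adjusted p = 0.0156, adjusted p = 0.466 with an estimated correlation) included Igf2bp2 (-0.84). Germline genes (3 of 20 rose, Nanos3 at 1.77, camera adjusted p = 0.012, adjusted p = 0.304 with an estimated correlation) passed as a list. So did mitochondrially encoded genes (none of 14 passed alone, median 0.795, camera adjusted p = 0.012, adjusted p = 0.607 with an estimated correlation). The mitochondrial share of counts was 0.324% in replicate 1 and 1.11% in replicate 2 of the DMSO group. Lists of formative, mesoderm, neural (median 0.07, mean 0.73, test lower), fibroblast, integrated stress response (median 0.08, mean -0.23, test lower) and interferon-stimulated genes (median 0.05, mean -0.15, test lower) did not pass camera (adjusted p = 0.579, 0.338, 0.509, 0.107, 0.12 and 0.429). Of these lists 1, 2, 3, 1, 6 and 1 genes fell and 1, 0, 2, 0, 1 and 0 rose by edgeR. Adjusted over the list alone 1, 4, 4, 1, 6 and 1 fell and 1, 1, 2, 0, 3 and 0 rose. The neural median was -0.00917 with 2 genes at their bound. For Ythdc1 4OHT vs DMSO in Dux-KO, 2890 of 29322 passed by edgeR, 1612 higher and 1278 lower. That balance depends on the scaling and the test: it was 1456 and 1498 with the authors' factors, 1466 and 1459 with RLE factors and 1666 and 1934 by DESeq2. Without DMSO replicate 2 it was 1076 and 1351. The count was 423 and 453 without 4OHT replicates 1 and 2, 779 without DMSO replicate 1. It was 4914 in a fit of these 4 libraries alone.

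**Figure D2:**
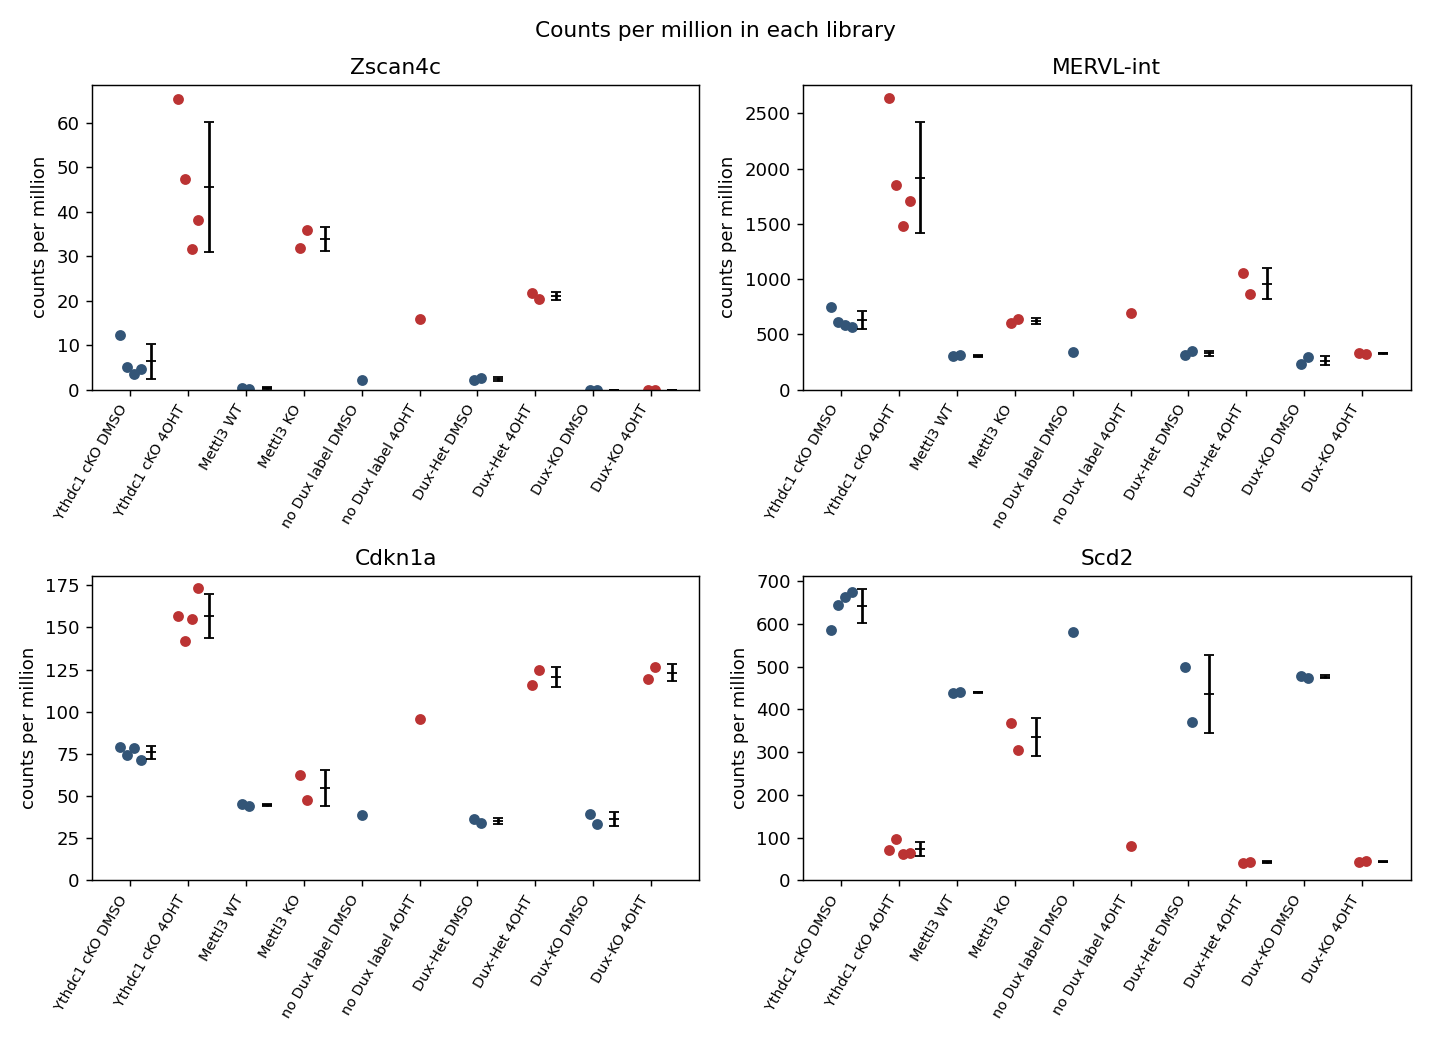
CPM of Zscan4c, MERVL-int, Cdkn1a and Scd2 in each library of 10 groups, with the mean and SD where a group has more than 1 library. Zscan4c had 0 counts in the Dux-KO libraries and 21 ± 0.837 CPM in Dux-Het under 4OHT.

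Dux-KO was then set against Dux-Het within each treatment (n = 2 each). Under 4OHT, Zscan4c was at least 741-fold lower (adjusted p = 1.86e-05 by edgeR's quasi-likelihood test), Zscan4d at least 539-fold and Zscan4f at least 378-fold. Duxf3 was lower (log2 fold change -4.39, SE 0.673, adjusted p = 0.019), and MERVL-int was 2.92-fold lower (SE of the log2 fold change 0.161, adjusted p = 0.00119), with MT2_Mm at -0.88. Of 40 two-cell-like genes 25 were lower (37 adjusted over the list alone). The median was -7.35, or -6.04 with 17 genes at their bound (camera adjusted p = 5.59e-83), and this was the list whose call held with an estimated correlation (adjusted p = 0.0484). With the replicate number as a block, 36.6% of those past the threshold were higher in Dux-KO under 4OHT and 53.8% under DMSO. That block was set within each genotype, so its error left out the spread between replicate numbers, which this difference still holds. These shares therefore cannot decide on the direction. In the fit without a block, of 29322 tested under 4OHT 80 were lower and 1 higher. These were 247 and 25 with no filter on low counts and 5 and 0 at a mean of at least 5 CPM. Without Dux-KO 4OHT replicate 1 or 2 the total was 30 or 32. Under DMSO, Zscan4c was at least 62.2-fold lower (adjusted p = 0.00188) and Zscan4d at least 49.8-fold. Of 40 two-cell-like genes 8 were lower there (24 adjusted over the list alone), with a median of -4.37, or -3.02 over 32 genes with 17 at their bound (camera adjusted p = 1.07e-24, adjusted p = 0.374 with an estimated correlation). MERVL-int (-0.32, adjusted p = 1) did not pass. In the fit without a block, 10 genes were lower and none higher under DMSO (87 and 37 with no filter), 4 without Dux-KO DMSO replicate 1 and 0 by edgeR without replicate 2. Cdkn1a did not pass in either treatment (0.03 and 0.07, adjusted p = 1 in both). Retroelement families passed camera as lower under 4OHT (2 of 22 lower, median -0.15, camera adjusted p = 2.75e-05, adjusted p = 0.682 with an estimated correlation) and under DMSO (0 of 22 by edgeR, 1 adjusted over the list alone, median -0.198, camera adjusted p = 8.21e-08, adjusted p = 0.374 with an estimated correlation). Under DMSO trophectoderm genes (median 0.499, camera adjusted p = 3.59e-05) and fibroblast and feeder genes (0.49, camera adjusted p = 4.1e-05) passed as higher with no member past the threshold (adjusted p = 0.374 with an estimated correlation for each). There ribosome biogenesis (-0.14, camera adjusted p = 0.00263), pluripotency (-0.155, camera adjusted p = 0.047) and m6A genes (-0.12, camera adjusted p = 0.047) passed as lower, again with no member past the threshold (adjusted p = 0.374, 0.374 and 0.408 with an estimated correlation). Under 4OHT formative (median 0.38, camera adjusted p = 0.00173) and primitive endoderm genes (0.22, camera adjusted p = 0.0351) passed as higher with no such member (adjusted p = 0.682 with an estimated correlation for each). Interferon-stimulated genes passed camera as higher under 4OHT (median 0.70) and DMSO (0.66) with no member past the threshold (adjusted p = 2.75e-05 and 4.93e-06, adjusted p = 0.682 and 0.374 with an estimated correlation).

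Whether the effect of 4OHT itself differs between the Dux genotypes was tested as an interaction. By edgeR 0 of 29322 passed (481 at an unadjusted p under 0.05), and DESeq2 called 2. MERVL-int had a difference of -1.22 (SE 0.223), Duxf3 of -3.94 (SE 1.15) and Cdkn1a of -0.03 (SE 0.2), each with an adjusted p of 1. Of the 42 two-cell-like genes found, 17 had 0 counts in all 4 Dux-KO libraries, where a ratio of ratios has no measured value. The simulation recovered 11.9% of 2-fold and 63.6% of 4-fold differences. The fold changes in Dux-Het and Dux-KO went together with r = 0.61 and rho = 0.692 across 29322 genes and repeat families, which are not independent replicates (r = 0.92 at a mean of at least 5 CPM). Higher in both were 974 against 80.5 expected, lower in both 898 against 55.5 expected, and 0 passed in opposite directions by edgeR. The expected counts take the calls of the Dux-Het and Dux-KO comparisons as independent. Both share an estimate of the spread for each gene, so the excess can be overstated. With the Ythdc1 set r was 0.729 for Dux-Het and 0.645 for Dux-KO across 24138, and with the Mettl3 set 0.292 and 0.22 across 23817.

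**Figure D3:**
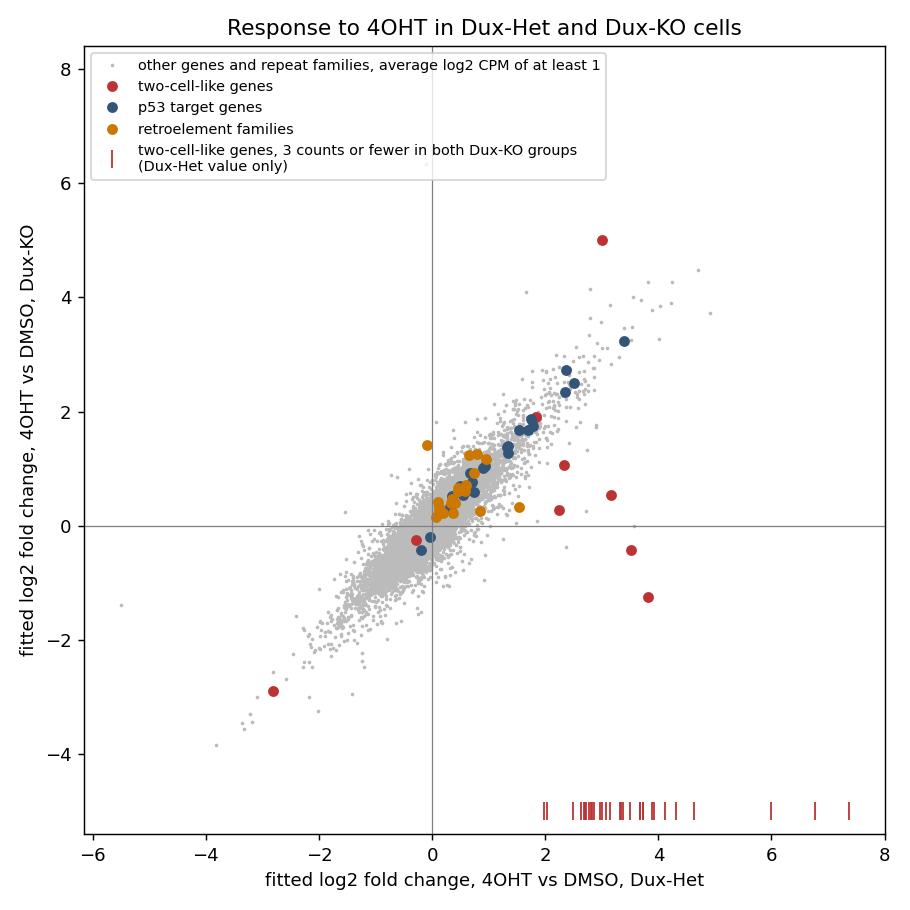
Log2 fold change after 4OHT in Dux-KO against Dux-Het, with two-cell-like genes, p53 targets and retroelement families in colour; ticks at the bottom are two-cell-like genes with 3 counts or fewer in both Dux-KO groups. MERVL-int had 1.545 in Dux-Het and 0.32 in Dux-KO.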

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

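In this part the tests of depth, of summed Zscan4 counts, of chromosomes and of p53 targets were chosen only after the result was seen; the other splits of the libraries, the 2 tests of repeat families and the list tests were set before. Of the 35 splits of the 8 Ythdc1 libraries into 4 and 4, 1, the real split, gave as many genes (11008), and the highest of the others gave 0. Every other split mixes 4OHT and DMSO libraries within a group, which widens the spread there. The smallest share this test can give is 1 in 35. It takes the 8 libraries as exchangeable, which the 2 ESC lines and the pairing of the numbers leave open, so chance is not excluded.

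Repeat families rose after 4OHT in the Ythdc1 set. The test took as its premise that intronic or unspliced RNA raises all families alike. The median of 313 endogenous retrovirus families (0.327) exceeded that of 101 DNA transposon, L2 and MIR families (0.203) by 0.124. The difference ranged from 0.104 to 0.135 leaving out 1 library. The premise itself was not tested, so the difference cannot exclude such RNA. Medians of endogenous retrovirus, DNA transposon, and L2 and MIR families were 0.373, 0.234 and 0.273 in Dux-Het. They were 0.459, 0.396 and 0.349 in Dux-KO. In the Ythdc1 set 32 of 93 DNA transposon families passed as higher and 1 as lower, and all 8 L2 and MIR families passed as higher. Intronic or unspliced RNA could account for that part of the rise. With scaling factors from genes alone the median of the repeat families was 0.308 (0.27 to 0.332 leaving out 1 library) against 0.285 in the fit reported. That argues only against the inclusion of repeat families in the scaling as the cause. Both fits used TMM, and a fit of gene entries alone moved fold changes little (median shift 0.0136 in log2). Other faults of the scaling were therefore not tested. A response to loss of Ythdc1 stays open as a hypothesis, and reads shared between copies were not tested.

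Two-cell-like genes were lower in Dux-KO than in Dux-Het cells. At the Dux-Het level the 2 Dux-KO DMSO libraries would hold 186.6 Zscan4c counts and held 0, which argues against depth. Counts shared out between near-identical copies would leave their sum in place, but the highest sum over 9 Zscan4 genes in a Dux-KO library under 4OHT was 0.0398 CPM, against at least 119.2 in Dux-Het. Loss of a single chromosome segment that held the genes themselves would gather them, yet 58 of the 78 lower genes with coordinates lay outside chromosome 7, which holds the most. Loss of a segment that holds a regulator of these genes would not gather them, so this count cannot decide on it. A need for Dux is the hypothesis that stays open, found and tested on the same libraries.

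Targets of p53 rose in the 3 sets treated with 4OHT. Their median in the Mettl3 set, which had no 4OHT, was 0.0285, with members on both sides. Trp53, which encodes p53, itself fell in that set (log2 fold change -1.001, adjusted p = 7.99e-05 by edgeR) and did not pass in the 4OHT sets (-0.05, -0.29 and -0.12). Exposure to 4OHT or Cre activity could raise them as well as loss of Ythdc1: these cannot be told apart, since the design holds no 4OHT library without the floxed allele.

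In the Ythdc1 set 8 named genes had 1 of 4 libraries far from the other 3, among 196 groups looked at, where 9.8 would be expected at 1 in 20. Of these, 3 were in replicate 1 of DMSO, which stood apart from the other DMSO libraries over all genes as well (chi-square per degree of freedom 30.97 to 37.05, against 8.441 to 10.82 among the others), and without it 10931 genes passed. In that library they were Scd1 at 103.3 CPM (others 163.3 to 171.7), Mesp2 at 2.273 (1.098 to 1.155) and Pax6 at 10.48 (4.758 to 5.724). In other DMSO libraries they were Dppa5a at 271.5 (249.6 to 251.6) and Chaf1b at 51.65 (44.87 to 45.19). Under 4OHT they were Fbp2 at 6.734 (3.084 to 3.234), Thy1 at 2.518 (0.9792 to 1.189) and Igf2bp3 at 70.38 (90.16 to 93.97). As a list, 5 of 17 differed between the Dux genotypes in their response to 4OHT by camera: two-cell-like genes (median -2.92, adjusted p = 8.54e-29, adjusted p = 0.279 with an estimated correlation), formative and primed epiblast genes (0.213, adjusted p = 0.00145, adjusted p = 0.802 with an estimated correlation), trophectoderm genes (-0.319, adjusted p = 0.0427, adjusted p = 0.813 with an estimated correlation), fibroblast and feeder genes (-0.471, adjusted p = 0.000176, adjusted p = 0.802 with an estimated correlation) and ribosome biogenesis genes (0.107, adjusted p = 0.0198, adjusted p = 0.813 with an estimated correlation). The value for two-cell-like genes cannot be read as a measured difference of effects, since 31 of its 40 members held 3 counts or fewer in both Dux-KO groups, where no fold can be given.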

How the results depend on the processing

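In this part the alternatives that drop the repeat families, the entries that resemble ribosomal RNA or 2 DMSO libraries (Dux-Het replicate 2 and Dux-KO replicate 1), the authors' factors, the block by column number in the Ythdc1 set and the other pseudocounts were chosen only after the results were seen. Over 376 pairs of a named gene and a comparison and 33 settings, 6465 values were compared. Of these 5837 kept their call, 448 grew weaker, 180 stronger, and 0 reversed direction. A change of sign counted as reversed only where the gene passed in either fit, and otherwise as kept. Genes named for a large change or a small adjusted p in these same libraries were unlikely to reverse. Counts of genes past the threshold moved as follows, and except where noted the cause was not tested. Tested against a 1.5-fold change, a stricter question, 2827 genes passed in the Ythdc1 set, 2159 in the Mettl3 set, 642 in Dux-Het, 609 in Dux-KO and 2525 for Ythdc1 minus Mettl3. With no filter on low counts 4319 passed for Ythdc1 4OHT vs DMSO in Dux-Het, 4701 for Ythdc1 4OHT vs DMSO in Dux-KO and 28 in the interaction. There 272 passed for Dux-KO vs Dux-Het under 4OHT and 124 for Dux-KO vs Dux-Het under DMSO. With at least 5 CPM these were 5 and 2, with fewer genes tested. DESeq2 gave 2 for the interaction and 17 under DMSO. With the replicate number as a block the counts were 6098 (Dux-Het), 6801 (Dux-KO) and 5 (interaction). Between genotypes they were 292 (4OHT, 107 higher and 185 lower) and 132 (DMSO, 71 higher and 61 lower). The block was set within each genotype, so it took the spread between replicate numbers out of the error. A difference between genotypes still holds that spread, so these 292 and 132 calls rest on too small an error. They cannot decide whether genes are higher in Dux-KO. The labels give the libraries of a pair only a number in common. Libraries of the same number had a correlation of 0.0824 in the Mettl3 set, 0.566 in Dux-Het and 0.243 in Dux-KO. With 2 libraries per group, both pairs share that 1 value by construction. A block by the title's replicate number was not run in the Ythdc1 set, since the columns cannot be traced to the titles. With the column number as a replicate block instead, 11904 passed there (6206 higher and 5698 lower, 10883 of them in both fits) and 7708 for Ythdc1 minus Mettl3 (4157 and 3551). Lists past camera were 9 and 5, and the changed list calls stand beside the results. Of the genes named for these 2 results Pou5f1 alone changed its call. Other list members changed theirs, among them Esrrb (adjusted p = 0.0182) and Klf4 (0.0165), which passed in the Ythdc1 set under the block, and Gdf15 (0.0526), which no longer passed for Ythdc1 minus Mettl3. Members that rose and fell were then 7 and 15 for pluripotency genes and 2 and 14 for ribosome biogenesis genes in the Ythdc1 set, and 17 p53 target genes were higher in the difference. In fits of a genotype alone 1032 passed in Dux-Het and 4914 in Dux-KO. Without the 2 DMSO libraries 1430 passed in Dux-KO and 1 under DMSO. The correlation of Dux-Het with Dux-KO was 0.92 at 5 CPM or more. Leaving out 1 library at a time gave 9910 to 10931 genes in the Ythdc1 set, 351 to 9716 in the Mettl3 set, 1254 to 2957 in Dux-Het, 423 to 3645 in Dux-KO, 0 to 1 for the interaction, 30 to 97 under 4OHT, 0 to 15 under DMSO and 5033 to 7295 for Ythdc1 minus Mettl3. Lists past camera, of 17, then ran from 6 to 8, 4 to 10, 7 to 10, 8 to 11, 2 to 10, 3 to 6, 1 to 12 and 3 to 6 in the same order. With an estimated correlation 0 lists passed camera in each result but 4OHT (1). By fry 10 lists passed in the Ythdc1 set, 1 in the Mettl3 set, 4 in Dux-KO, 0 in the interaction, 1 under 4OHT and 0 under DMSO; by its mixed test these were 17 (Ythdc1), 17 (Mettl3), 0 (interaction), 2 (4OHT), 1 (DMSO) and 15 (Ythdc1 minus Mettl3). Groups left with a single library were assumed to vary like the others. Not run for lack of the ESC line in the columns were results for line 1, line 2 and their difference and the additive line model; pseudocounts laid out for normalized values were not needed for the tests, which use counts. In the pair with no Dux label, pseudocounts of 0.1 and 1 CPM gave list medians of 2.41 and 1.23 for two-cell-like genes, 0.488 and 0.306 for primitive endoderm genes and -0.532 and -0.266 for neural genes. Depth sets the floor of 3 counts for genes at 0. Recovery of 1.5-fold changes in simulation did not follow depth: it was 29.9% in the Mettl3 set (24.96 to 28.66 M) and 5.97% and 2.99% in the deeper Dux set (31.64 to 54.14 M).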

Other observations

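In this part all tests were chosen only after the result was seen. Genes of sterol synthesis, the pathway that makes cholesterol, fell after 4OHT in the Ythdc1 set: all 23 passed as lower (median -1.74, camera adjusted p = 1.4e-23, adjusted p = 0.0313 with an estimated correlation), among them Insig1 (-2.47), Idi1 (-2.22), Hmgcs1 (-2.12) and Sqle (-1.72). The hypothesis that the fall goes with 4OHT treatment of Ythdc1 cKO cells, and not with that set of libraries, was tested in Dux-Het, where 22 fell with a median of -1.63 (camera adjusted p = 6.13e-31, adjusted p = 0.00607 with an estimated correlation). In Dux-KO 22 fell as well (-1.67, adjusted p = 0.00584 with an estimated correlation). In the Mettl3 set 16 fell and 3 rose (-0.518, adjusted p = 0.0347 with an estimated correlation), and Sqle (0.26, adjusted p = 0.0516 by edgeR) did not pass. As with p53 targets, no library separates 4OHT from the Ythdc1 cKO genotype.

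Glycolysis genes fell in the Mettl3 set, 16 lower and 1 higher of 18 (median -1.2, camera adjusted p = 5.35e-16, adjusted p = 0.0347 with an estimated correlation), with the phosphofructokinase gene Pfkp at -2.52, the lactate dehydrogenase gene Ldha at -1.79 and Pgk1 at -1.09. The hypothesis that the fall is shared with Ythdc1 cKO cells was tested in the Ythdc1 set, where 16 fell and none rose (median -0.661, camera adjusted p = 5.61e-13, adjusted p = 0.0597 with an estimated correlation). In Dux-Het and Dux-KO 13 fell in each (-0.94 and -1.07, adjusted p = 0.0161 and 0.0123 with an estimated correlation).

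In the pair with no Dux label (1 library each, no test) Ythdc1 stood at 58.4 CPM (56 to 60.8) under DMSO and 46.8 (44.8 to 48.8) under 4OHT, Zscan4c at 2.25 (1.8 to 2.77) and 15.9 (14.8 to 17.2), MERVL-int at 337.5 and 697, Cdkn1a at 38.7 and 95.7, Mdm2 at 54.4 and 225, Scd2 at 581 and 79.9 and Nanog at 243.5 and 158. The medians of two-cell-like genes (1.58, 37 of 40 higher), p53 target genes (0.592, 21 of 23) and retroelement families (0.363, 20 of 22) lay at percentile 100 of random lists, those of neural genes (-0.459) and trophectoderm genes (-0.386) at 0.02 and 0.03. Mitochondrially encoded (0.342), primitive endoderm (0.325) and interferon-stimulated genes (0.383) lay at 99.97, 99.46 and 99.45, and ribosome biogenesis (-0.384), silencing (-0.335) and fibroblast and feeder genes (-0.286) at 0.21, 0.67 and 0.85. The other 6 lists lay between 5.32 and 53.84. The rRNA-like Gm26917 held 11.5% of counts in Dux-KO DMSO replicate 1 and 5.80% in replicate 2.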
